A study of Mus musculus with 8 samples.

How the data were processed

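Total RNA from 8 tumours of 4T1 cells, a mouse mammary carcinoma line, was measured on 1-colour (Cy3) Agilent mouse arrays. Per the labels, the cells had been infected for 24 h at a multiplicity of 50 with an empty adenovirus (4 control arrays) or with an adenovirus carrying PRH (4 PRH arrays), injected into a mammary fat pad of female BALB/c mice, and the tumours were taken on day 22. PRH is the protein of the gene Hhex. Each array carries a mouse number, 1, 2, 3 or 5, and both groups hold the same 4 numbers. The labels differ on the material: the series' design text has RNA extracted from each tumour, while the extraction protocol names endothelial isolates, so which of these was on the arrays is not settled here. The design text also calls the arrays human, but the probes carry mouse accessions.

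The scanner files hold spot intensities on a linear scale. Per the file headers, the deposited intensities were made with Agilent Feature Extraction 10.7.3.1 on an array design placed on the mouse build mm9. The submitters' processing notes name version 9.1. The processed signal is the scanner software's background-corrected intensity, per the file headers. A table of the authors' normalized values was also deposited. Its values are linear intensities whose medians lay between 123.83 and 125.9 over the 8 arrays, and its rank correlation with the scanner values of the same array was 0.9888 to 0.9954. Its background correction and any added offset stay unknown, since the labels say only that the data were normalised in R.

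All 8 arrays lay on 1 slide and came from 1 scan. The control arrays filled slide column 2 and the PRH arrays slide column 1, and the mouse numbers followed the slide rows, so slide column and group cannot be told apart and a mouse number is also a slide row. No spot was saturated. Between 64.17% and 73.9% of the 55681 non-control probes were well above background on an array. The number of arrays, 4 a group, limits the precision. P-values measure the spread between these tumours, with 1 control and 1 PRH array a mouse number.

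The main values were log2 of the processed signal minus the array's 75th percentile of it over non-control probes. Control spots were left out, an outlier spot was left out where its probe had other spots, and the spots of a probe were averaged. A probe was tested if it was well above background on at least 4 of the 8 arrays, which kept 39463 probes. The files hold no gene symbols. Probes were named through the RefSeq accessions in the files and a RefSeq gene table of assembly GRCm38.p6, used for names alone. Of 26392 probes with a curated RefSeq mRNA accession, 25869 matched, and 26582 probes matched a symbol in all. Of the probes without a symbol, 16194 are named in the files by a genomic interval. A gene with several probes was represented by its brightest one (4126 tested genes had more than 1 probe past the filter), and other probes are given where their sign is the opposite. This left 34543 tested items, 16377 named genes and 18166 unnamed probes.

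Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment, threshold 0.05). Adjusted p-values below come from this fit. The model held the group alone. Values of a few measures per array were compared with an exact two-sided permutation test over 70 arrangements, whose smallest p is 0.0286. This test takes the arrays as unpaired throughout. With the mouse numbers as pairs, too few arrangements exist for a p under 0.05, and no such test was run. Where a probe was not well above background on any array of a group, only a bound is given: the bright group's mean against the mean, per array, of the higher of the probe's own signal and the lowest signal among probes well above background. The 39 gene lists, 21 of pathways and 18 of cell types, the alternatives and the rule for named genes were fixed before the data were examined. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, whose directional test is meant unless stated. Named genes are Hhex and the measured members of a list of proposed PRH targets, the 12 largest differences in each direction among named genes that passed with no overlap between the groups (1531 higher and 1985 lower met this), and up to 4 members with the smallest p of each list described. The rule gives 187 genes. Of them 108 passed, and all of these but 3 are named, while of the list members that did not pass only some are, chosen after their values were seen, and the counts of calls that held cover all 187.

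Whether a mouse number pairs the arrays was checked from the deviations of each array from its group mean. The correlation of the same-numbered control and PRH arrays was 0.203, 0.436, 0.665 and 0.274 for numbers 1, 2, 3 and 5, all above 0.1, and 6 of 8 arrays correlated best with their own number. By the rule set for this, the numbers pair the samples. The pairing comes from the number in the labels, which is shared with the slide row, and values with the mouse number as a block are printed, with few exceptions, where they change a call or move a count by over 1.5 times.

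Alternatives were quantile normalization, normexp (offset 50) with quantile normalization, the authors' values, median centring, no filter on dim probes, probes above background on all 8 arrays, the mean of a gene's probes, an intensity trend with robust variance, array weights, the mouse number as a block, every probe tested separately, and leaving out each array. The files hold median signals but no mean signals, so normexp was run on the median signal and the background median. A block by slide or scan could not be fitted with 1 slide and 1 scan. Centring on spike-in control probes and testing named genes alone were added after seeing the data. The fits were tested on simulated data for the PRH comparison, with 200 changed items among 34543. The share recovered was 19% at a log2 change of 1 and 58% at a log2 change of 2, with 7 false calls, and 0 calls were made with no change put in. The noise was drawn independently for each item. The simulation can therefore not show false calls from effects shared across an array, nor the share recovered where far more items change. No array was a copy of another: no spot values were shared, and the smallest SD of log2 differences between a pair of arrays was 0.623.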

Results

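Gene expression was measured in 8 tumours grown from 4T1 cells, a mouse mammary carcinoma line, after the cells had been infected with an empty adenovirus (control, n = 4) or with an adenovirus carrying PRH (n = 4). PRH, the protein of Hhex, is a homeodomain transcription factor, and the series asks which genes differ in tumours meant to overexpress it. The brighter part of the signal differed between the groups and the median signal did not pass (104 ± 7.53 in control and 95.08 ± 5.05, n = 4 each, exact permutation p = 0.143). The 75th percentile of the signal was 1094 ± 131 on the control arrays and 722.4 ± 41.2 on the PRH arrays (mean ± SD, n = 4 each, exact permutation p = 0.0286), while the share of probes well above background was 66.7% ± 2.3 against 73.18% ± 0.777 (exact permutation p = 0.0286). Control arrays lay in 1 slide column and PRH arrays in the other, so slide column and group cannot be told apart in any comparison that follows. Arrays correlated at 0.912 to 0.982 within groups and at 0.903 to 0.963 between groups (Pearson r across probes, which are not independent replicates).

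Hhex read lower, not higher, on the arrays labelled PRH. Its 1 probe stood at -0.58 ± 0.20 in control and at -1.67 ± 0.14 in PRH-labelled tumours (log2 relative to the array's 75th percentile, mean ± SD, n = 4 each), a difference of -1.09 (SE 0.149), or 2.13-fold, with no overlap between the groups. It passed with limma (adjusted p = 0.00686) and in all 5 scalings, and the exact permutation p was 0.0286, the smallest possible with 4 against 4 unpaired arrays. A delivered gene that the probe still read would give the opposite direction, so tumours are called PRH-labelled throughout. Every direction below is that of the label. The cells were infected for 24 h before injection and the tumours were taken on day 22. Whether the delivered gene was still expressed then was not tested. Whether the probe reads the delivered cDNA is not known from the files, and the call was lost when arrays were centred on their spike-in probes (difference -1.22, adjusted p = 0.142). With that centring only 1 of 34543 items passed, so the loss was not particular to Hhex.

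Among 14 measured genes proposed as PRH targets, 3 were higher and 1 was lower in PRH-labelled tumours, and adjusted over the list alone the counts were again 3 and 1. Tle4, a Groucho-family corepressor, rose by 1.19 on the log2 scale (SE 0.199, adjusted p = 0.00785), but its other probe passed in the opposite direction (-1.12). Kdr, the main endothelial receptor for VEGF, was higher by 1.17 (SE 0.296, adjusted p = 0.0248). Slc10a1, a bile acid transporter of hepatocytes, was higher by 0.73 (SE 0.152, adjusted p = 0.0131). Its probe was about as bright as that of Gapdh, at 8.03 in control and 8.76 in PRH-labelled tumours against 8.11 and 8.62. Whether this probe reads Slc10a1 was not tested. Tle1, another Groucho-family corepressor, was lower by -0.70 (SE 0.190, adjusted p = 0.032). Kdr did not pass after median centring, its other probe stood at -0.48, and Kdr and Tle1 each failed in 6 of the 8 fits without 1 array, with adjusted p up to 0.0685 (without control 2) and 0.084 (without PRH 1). Slc10a1 passed in the 75th percentile scaling alone of the 5, and the other probes of Tle1 stood at -0.14 and 0.33.

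The remaining 10 target genes did not pass. The VEGF receptor gene Flt1 differed by -0.06 (SE 0.171) and the growth factor gene Vegfa by -0.03 (SE 0.202, another probe at 0.24), and both signs changed with the scaling. The endothelial co-receptor gene Eng differed by 0.09 (SE 0.205), with the sign turned after median centring, and the receptor genes Tie1, Tek and Nrp1 by -0.09 (SE 0.330), -0.52 (SE 0.428) and -0.55 (SE 0.231). The endothelial genes Cldn5 and Esm1 stood at 0.98 (SE 0.564) and 0.77 (SE 0.552), Myc at -0.18 (SE 0.151) and Tg, the thyroglobulin gene, at -0.34 (SE 0.285). As a set the targets did not stand apart from other genes (camera adjusted p = 0.742, median difference -0.04, mean 0.18). Leaving out control 2 brought Esm1 past the threshold (adjusted p = 0.0399), and leaving out control 3 did so for Tek (adjusted p = 0.0305). Other scalings brought Nrp1 (normexp, the authors' values and median centring), Tg (quantile normalization) and Myc (median centring) past it.

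**Figure D1:**
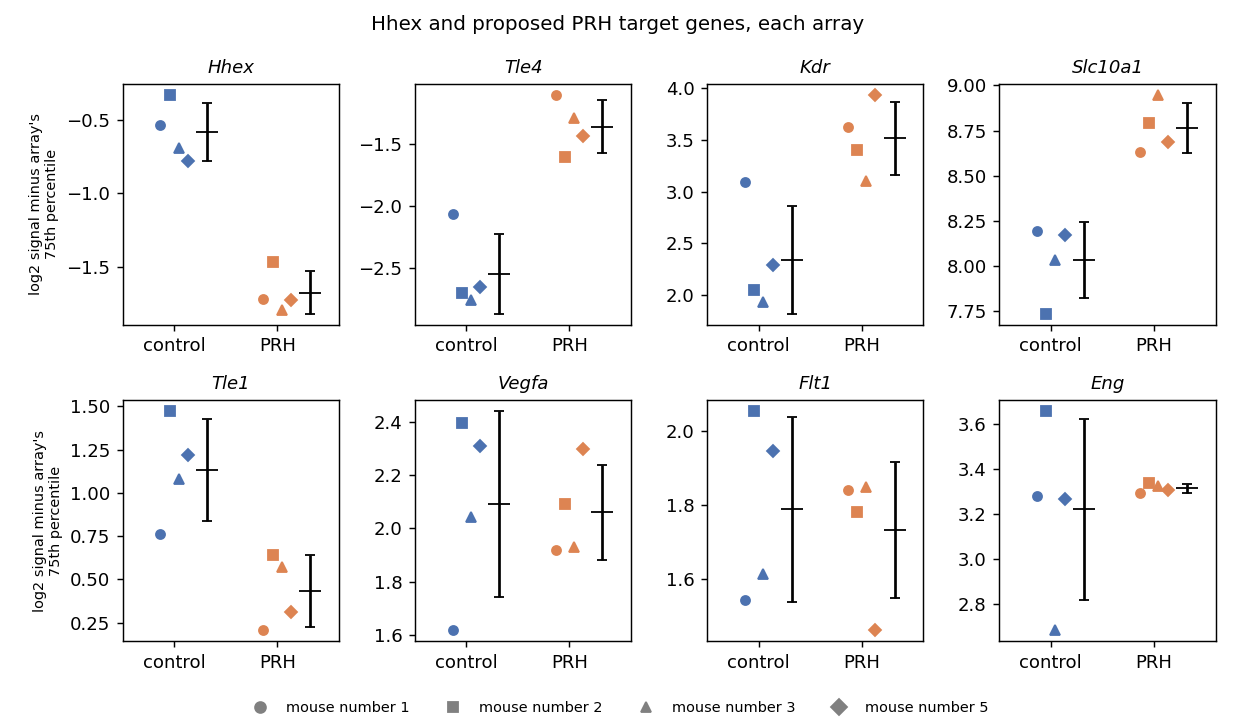
Level of Hhex and 7 proposed target genes on each array (y axis, log2 signal minus the array's 75th percentile; x axis, group), with points for arrays by mouse number and bars for mean ± SD (n = 4). The 4 PRH-labelled arrays lie below the 4 control arrays for Hhex and Tle1 and above them for Tle4, Kdr and Slc10a1, while Vegfa, Flt1 and Eng overlap.

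Of the 12 largest rises in PRH-labelled tumours 4 were in genes of keratinocytes, a grouping made after their values were seen. Of the 11 genes of the fixed skin list 0 passed with limma. Trex2, a DNA exonuclease of keratinocytes, rose by 3.83 (SE 0.818, adjusted p = 0.0143), with 2 of 4 control arrays well above background. Cnfn, which encodes cornifelin of the cornified envelope, was higher by 2.47 (SE 0.622, adjusted p = 0.0246), and Klk9, a kallikrein-related peptidase, rose by 2.83 (SE 0.624, adjusted p = 0.0157). Lce3c, a late cornified envelope gene, was higher by 3.43 (SE 1.01, adjusted p = 0.0418), with 3 of 4 control arrays above background. Cnfn failed in 3 of the 8 fits without 1 array, those without control 2 (adjusted p = 0.0684), control 3 and PRH 2, and Lce3c failed in 7 of them, with adjusted p up to 0.0883 (without control 3), and in the 4 other scalings.

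Other large rises were spread over unrelated genes. Cabp5, a calcium-binding protein gene of the retina, rose by 2.45 (SE 0.240), the adaptor gene Shc4 by 2.44 (SE 0.261) and the sialyltransferase gene St6galnac1 by 2.44 (SE 0.256), all with adjusted p = 0.00686. Their other probes were also higher, by 1.00, 1.17 and 0.60. The olfactory receptor genes Olfr222 and Olfr1472 and the gene Lrrd1 were well above background on 0 of 4 control and 4 of 4 PRH-labelled arrays, and were at least 3.07-fold, 3.33-fold and 2.39-fold higher (adjusted p = 0.00686, 0.00897 and 0.00686). Olfr222 did not pass with normexp. Ugt2b35, a glucuronosyltransferase gene above background on 1 of 4 control arrays, was higher by 2.48 (SE 0.658, adjusted p = 0.0296) but failed with normexp, with the authors' values and in 7 of 8 fits without 1 array, with adjusted p up to 0.0801 (without control 2).

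The 12 largest falls were in genes of varied function. Ciart, a circadian repressor, fell by 3.06 (SE 0.622, adjusted p = 0.0124), Cbx8, a Polycomb protein gene, by 3.00 (SE 0.462, adjusted p = 0.00719) and Rrm2b, a ribonucleotide reductase subunit gene that p53 induces, by 2.83 (SE 0.599, adjusted p = 0.0138), each above background on 1 of 4 PRH-labelled arrays. Btla, an inhibitory receptor of lymphocytes, fell by 2.61 (SE 0.586, adjusted p = 0.0167) and Sh2d1a, an adaptor of T and NK cells, by 2.42 (SE 0.525, adjusted p = 0.015, above background on 2 of 4 PRH-labelled arrays). Gtse1, a gene of the G2 and S phases, fell by 2.34 (SE 0.455, adjusted p = 0.0109) and the kinase gene Lmtk2 by 2.81 (SE 0.449, adjusted p = 0.0074), both above background on 2 of 4 PRH-labelled arrays. Manea, an endomannosidase gene, fell by 2.64 (SE 0.226, adjusted p = 0.00686) and the melanocortin receptor gene Mc3r by 2.52 (SE 0.307, adjusted p = 0.00686). Mgme1, a mitochondrial exonuclease gene, Spire2, an actin nucleator gene, and the cadherin gene Cdh17 were above background on no PRH-labelled array and were at least 3.99-fold, 4.04-fold and 3.54-fold lower (adjusted p = 0.00888, 0.0116 and 0.0135). These 12 genes passed in all 5 scalings, in all 8 fits without 1 array and with the mouse number as a block.

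Across the array, 8934 of 34543 tested items passed, 5938 higher and 2996 lower in PRH-labelled tumours, and 13438 had an unadjusted p under 0.05. Named genes went down somewhat more often than up, with 1729 of 16377 higher and 2108 lower, whereas of the 18166 unnamed probes 4209 were higher and 888 lower. In 31.401% of the items the groups did not overlap, against 2.8571% by chance. The directions hung on the scaling. The median difference of all items was 0.29 after 75th percentile scaling, -0.18 after median centring, 0.07 after quantile normalization, 0.06 with normexp and 0.06 in the authors' values. The split of higher and lower calls was 2926 and 7612 after median centring, 4239 and 4431 after quantile normalization, 3731 and 4364 with normexp, and 3666 and 4392 in the authors' values. Called the same way in all 5 scalings were 2034 items higher and 2663 lower, of which 477 and 1848 were named genes, and no item was called in opposite directions. With the mouse number as a block, 12232 items passed, 9283 higher and 2949 lower. Without single arrays the count ran from 5733 (without PRH 1) to 11467 (without control 1), with 5828 without control 2 and 5774 without control 5, and centring on spike-in probes left 1. That 1 item, chosen after its value was seen, also had the lowest p of the main fit. It is the unnamed probe A_30_P01018426, placed by the file in mm9 on chromosome 14 from 106250821 to 106261843, well above background on 4 of 4 control and 0 of 4 PRH-labelled arrays and at least 12.3-fold lower (adjusted p = 0.00607).

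After 75th percentile scaling, dim probes, probes without a gene symbol and receptor genes read higher on the PRH-labelled arrays. The 75th percentile itself was lower there (722.4 against 1094 in control), which raises every scaled value of these arrays. Without scaling, the median signal was not higher there (95.08 against 104). Over 10 bins of brightness, the median difference of all items went from 0.91 in the dimmest to -0.14 in the 8th and 0.07 in the brightest. The 474 tested olfactory, vomeronasal and trace amine receptor genes, which encode sensory receptors, had a median difference of 1.12, with 163 higher and 2 lower, and 71 higher in all 5 scalings. Compared on each array with other named genes of the same brightness bin, the median receptor gene stood at -0.47 ± 0.27 in control and 0.39 ± 0.17 in PRH-labelled tumours (n = 4 each, exact permutation p = 0.0286). The 4 PRH-labelled arrays alone can bring a dim probe of any class past the filter, so these values rest on a selected set. Without the filter, 1459 receptor gene probes rose by 0.988 and 96 synthetic control probes named ERCC by 0.849. The gap of 0.139 overlapped between groups (exact permutation p = 0.2). The 9926 probes named by a genomic interval had a median difference of 0.78, and the 15903 other named genes one of -0.04. Of 7 spike-in probes detected on all arrays, taken relative to their own mean, 5 differed between the groups without overlap, by -0.42 to 0.41 (exact permutation p = 0.0286 each, 0.04 after Benjamini-Hochberg adjustment over 7). The dimmer of these 5 were higher on the PRH-labelled arrays (0.129, 0.41 and 0.104) and the brighter lower (-0.172 and -0.424).

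**Figure D2:**
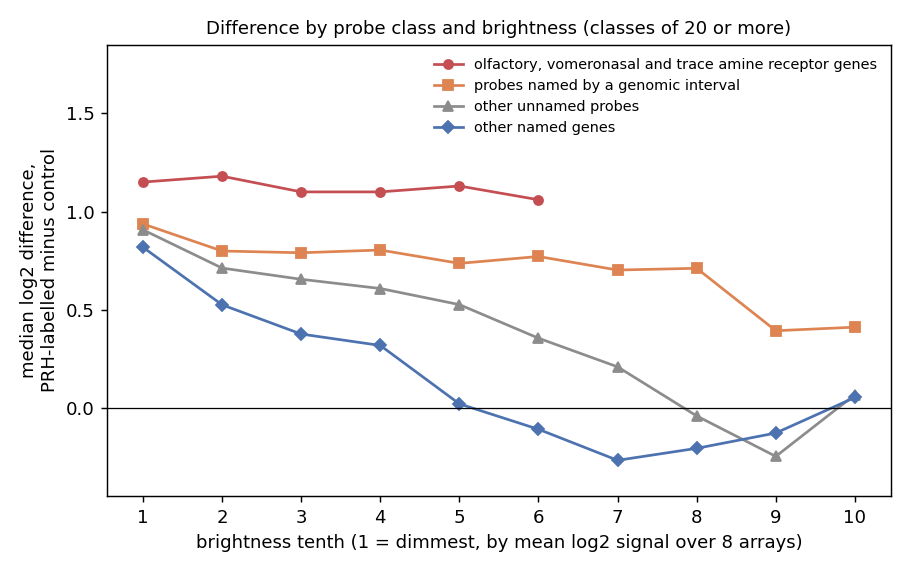
Median log2 difference, PRH-labelled minus control (y axis), in 10 bins of brightness over the 8 arrays (x axis, 1 is the dimmest), for receptor genes, interval-named probes, other unnamed probes and other named genes, where a class had at least 20 members. Receptor genes lie above 1.0 up to the 6th bin, while other named genes go from 0.82 in the dimmest bin to -0.27 in the 7th.

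Genes of cell division and of 3 stress and early responses gave 4 of the 9 list calls made with a preset correlation, none of which held with an estimated one (adjusted p = 0.929 each), and few of their members moved. Of 28 cell cycle genes 1 was higher and 5 were lower: Cdk1, the mitotic kinase, fell by 1.63 (SE 0.334, adjusted p = 0.0125), with other probes at -0.71 and 0.82, Mcm3, a subunit of the replicative helicase, was lower by -1.30 (SE 0.297, adjusted p = 0.0178), and Tyms, thymidylate synthase, was higher by 0.84 (adjusted p = 0.0108). Of 17 p53 response genes 1 was higher and 4 were lower, among them Zmat3 (-1.12, adjusted p = 0.00708) and Ei24 (-1.32, adjusted p = 0.0123). Of 19 immediate early genes 4 fell and 0 rose, among them the mRNA decay factor gene Zfp36 (-1.66, adjusted p = 0.00952) and the antiproliferative gene Btg2 (-1.20, adjusted p = 0.00721). Of 17 unfolded protein response genes 2 were lower, led by Herpud1, a gene of endoplasmic reticulum degradation (-1.32, adjusted p = 0.00686). Adjusted over the list alone, the higher and lower counts were 1 and 5, 1 and 6, 0 and 4, and 0 and 1. Mcm3 failed without PRH 1 (adjusted p = 0.0511) and without control 5 (0.0501), and Tyms failed after median centring.

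Of 24 ribosomal protein genes 11 were higher and 1 was lower, with Rps16 at 0.69 (adjusted p = 0.00932), Rpl13 at 0.65 (0.0107, other probes at -0.58 and 0.61) and Rpl10a at 0.53 (0.0134), but none of the 24 was called in all 5 scalings, and after quantile normalization, with normexp and in the authors' values the list's median lay below that of all items. Of 21 ribosome biogenesis genes 1 was higher and 3 were lower. Adjusted over the list alone, the counts were 14 and 1 for ribosomal proteins and 0 and 0 for ribosome biogenesis. Of 24 collagen and matrix genes 2 fell, Col15a1 (-1.23, adjusted p = 0.00722) and the fibrillin gene Fbn1 (-0.88, adjusted p = 0.0072), also 2 over the list alone, and another probe of Col15a1 stood at 0.24. In cholesterol synthesis 0 of 20 passed, and 0 over the list alone. In oxidative phosphorylation 1 of 25 was higher, Cox4i1 (0.83, adjusted p = 0.00722, lost after median centring), and 2 were lower, led by Sdha (-0.78, adjusted p = 0.0131), with 1 and 1 over the list alone.

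With camera, 9 of 38 tested lists passed. Ribosomal proteins (adjusted p = 0.00926) stood above the other genes. Cell cycle (0.00309), collagen and matrix (0.0232), ribosome biogenesis, p53 response and unfolded protein response (0.0331 each), immediate early response (0.0368), and cholesterol synthesis and oxidative phosphorylation (0.0441 each) stood below them. None of the 9 calls held with an estimated correlation (adjusted p = 0.929 each), and quantile normalization, normexp and the authors' values gave 0 camera calls. The directional test of fry called ribosomal proteins alone (adjusted p = 0.00981). Its mixed test, which takes changes in either direction and sets no list against other genes, passed for most lists. Among them were the PRH targets (adjusted p = 0.000679) and type I interferon (3.68e-05), but not the cell cycle (0.105) or endothelial cells (0.381). With named genes alone as the background, 1 list passed, ribosomal proteins, and with the mouse number as a block that list did not pass (adjusted p = 0.0545) while the mesenchymal transition (0.033) and fatty acid (0.031) lists did. These 2 lists also passed in other alternatives, such as median centring (adjusted p = 0.0181 and 0.0239), and the macrophage list did without the filter (0.0477), with the mean of a gene's probes (0.0344) and without control 5 (0.0404), PRH 1 (0.0417) or PRH 2 (0.0334). The NK list passed without control 5 (0.0396) or PRH 1 (0.0417), the T cell list without control 5 (0.0283) and the neutrophil list without control 3 (0.0332). In 29 of the 35 splits of the 8 arrays into 4 and 4, the real one included, camera called at least 9 lists.

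Other pathway lists did not pass with camera in the main fit, though members did. The fatty acid list had 2 of 20 higher and 4 lower, with Cpt1b, of mitochondrial fatty acid import, up by 1.41 (adjusted p = 0.0116), and the lipase gene Pnpla2 (-0.76, adjusted p = 0.00786) and malic enzyme gene Me1 (-1.08, adjusted p = 0.00803) down (list adjusted p = 0.0501). Of 21 mesenchymal transition genes 1 was higher and 4 were lower, among them the repressor gene Zeb2 (-1.02, adjusted p = 0.0123) and Mmp2, a matrix metalloproteinase gene (-1.22, adjusted p = 0.0192, lost without PRH 1 at 0.0509), and the list's adjusted p was 0.0566. Angiogenesis ligands had 0 of 26 higher and 2 lower, with Angpt1, a ligand of the receptor Tek, at -1.35 (adjusted p = 0.0102, list 0.618). The Wnt list had 2 of 21 higher and 2 lower, with the receptor gene Fzd1 at -1.25 (adjusted p = 0.00686) and the inhibitor gene Dkk1, above background on 0 of 4 control arrays, at least 2.72-fold higher (adjusted p = 0.00852, lost with normexp and in the authors' values, list 0.238). Over the list alone, the higher and lower counts of these were 2 and 4, 1 and 5, 0 and 1, and 1 and 1. The TGF-beta list had 1 of 19 higher and 3 lower (list 0.328) and the hypoxia and glycolysis list 3 of 23 higher and 2 lower, with the enolase gene Eno1 at 0.79 (adjusted p = 0.0148, lost with normexp, in the authors' values and after median centring, list 0.65).

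Interferon and inflammatory genes showed few differences. Of 22 type I interferon genes 3 were higher and 0 lower, with the interferon-induced protease gene Usp18 at 0.72 (adjusted p = 0.00794, lost after median centring), and the list's adjusted p was 0.742. Of 19 genes of interferon gamma and antigen presentation 1 was higher (list 0.425), of 23 cytokines and chemokines 1, Tnf, was higher by 0.70 (adjusted p = 0.0153, list 0.618), and of 13 heat shock genes 1, Hsp90ab1, was higher by 0.77 (adjusted p = 0.00783, list 0.684). Tnf passed in the 75th percentile scaling alone, and Hsp90ab1 failed with normexp, in the authors' values and after median centring. Adjusted over the list alone, the TGF-beta counts were 1 and 3, hypoxia 3 and 2, type I interferon 3 and 0, interferon gamma 0 and 0, cytokines 1 and 0, and heat shock 1 and 0. As camera sets a list against all items, whose median was 0.29, lists with a median above 0, such as hypoxia (0.14), cytokines (0.09) and angiogenesis ligands (0.06), were tested as lower.

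Other pathway members that the rule for named genes gives also passed, but each failed in 2 to 7 of the 8 fits without 1 array, with adjusted p up to 0.118 (Ddx21, without control 2). Lower were Bub1b of the spindle checkpoint (-0.71), the p53 target Pmaip1 (-0.59), the immediate early genes Klf4 (-0.75) and Dusp1 (-0.70), and the chaperone gene Dnajb9 (-0.64). Also lower were the nucleolar genes Nop58 (-0.59), Ncl (-0.52) and Ddx21 (-0.69), Atp5a1 of the ATP synthase (-0.71), Lox (-0.76) and Mmp14 (-0.52) of matrix remodelling, Id2 (-0.78), Smad7 (-0.98) and Tgfbr2 (-0.47, another probe at 0.27) of TGF-beta signalling, the Wnt target Lgr5 (-1.03), the oxygen sensor gene Egln1 (-0.77) and the ephrin gene Efnb2 (-1.05, another probe called at 0.86). Higher were the p53 target Bbc3 (0.61), the nucleolar gene Nop56 (0.67, another probe at -0.16), the lipid regulator gene Ppara (0.95), and the receptor gene Acvrl1 (0.64). Also higher were the Wnt target Axin2 (1.28, 1 of 4 control arrays above background), Gapdh (0.50, other probes from -0.48 to 0.43) and Bnip3 (0.77) of the hypoxia list, the interferon genes Isg15 (0.51) and Psmb8 (0.51), and the keratin gene Krt18 (0.52). Of the higher ones, all 10 named here failed after median centring, and Gapdh, Krt18, Axin2 and Psmb8 passed in the 75th percentile scaling alone. Of the lower ones, Dnajb9, Ddx21 and Tgfbr2 failed with normexp and in the authors' values, and Mmp14 in the latter. With the mouse number as a block, Gapdh (adjusted p = 0.051), Bub1b (0.0519), Mmp14 (0.0519), Tgfbr2 (0.0655), Psmb8 (0.0571), Dnajb9 (0.0561), Dusp1 (0.0503), Ppara (0.0525) and Ncl (0.0563) did not pass. The chaperone gene Hspa8 did (0.43, other probes at -0.36 and -0.26, adjusted p = 0.0487 against 0.0674). The block moved the count of lower genes from 5 to 3 in the cell cycle, from 2 to 1 in the unfolded protein response and from 1 to 0 in ribosomal proteins. It moved that of higher genes from 1 to 0 in interferon gamma and antigen presentation, from 1 to 2 in heat shock, from 0 to 1 in the immediate early response and from 2 to 1 in the fatty acid list.

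**Figure D3:**
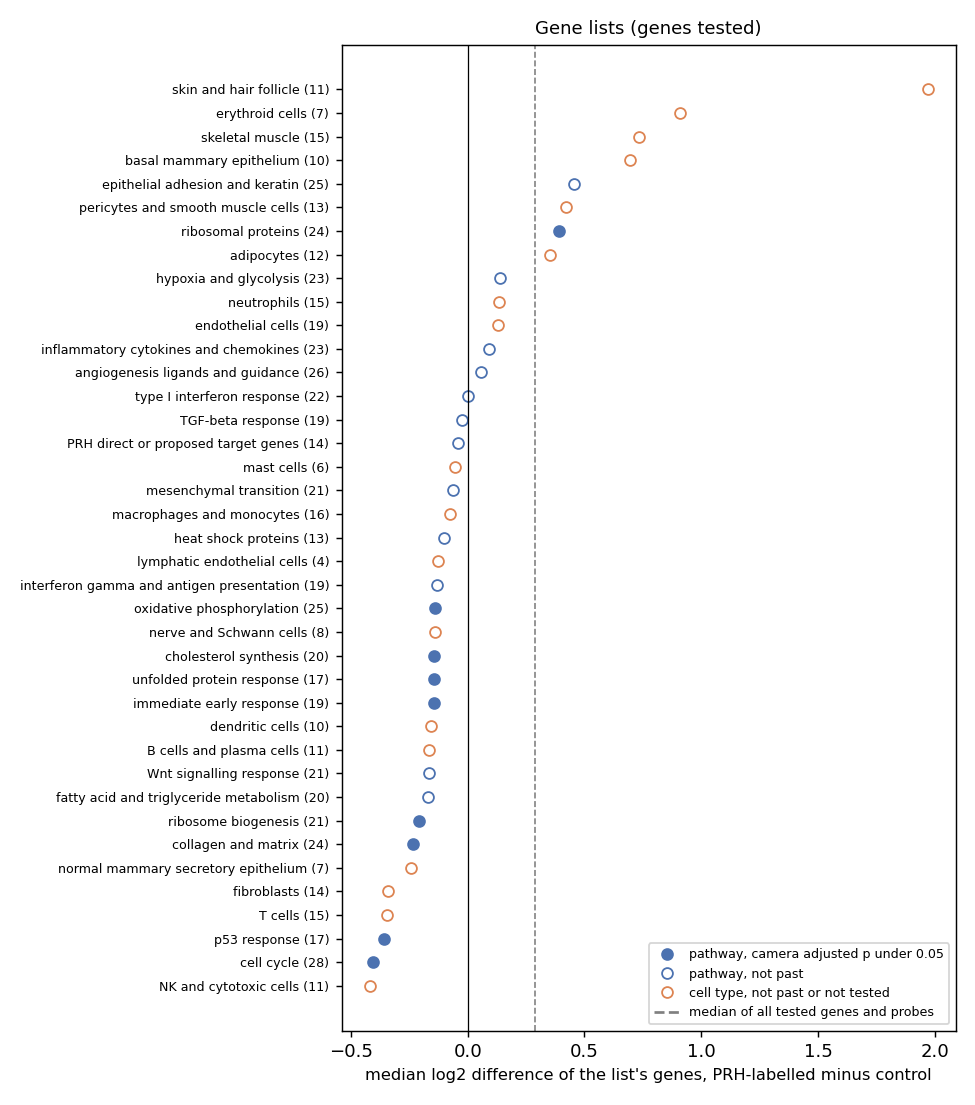
Median log2 difference, PRH-labelled minus control, of the tested genes of each of 39 lists (x axis), with the number of genes tested in parentheses, pathway lists in blue and cell type lists in orange. Filled points are the 9 lists that camera called in the main fit, and the dashed line is the median of all items, 0.29, which moves to -0.18 after median centring.

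Markers of other cell types give the makeup of the samples, and no cell type list passed with camera in the main fit. Endothelial markers had 1 of 19 higher, Kdr, and 0 lower (0 over the list alone), and the mean over the list was 1.14 ± 0.64 in control and 1.36 ± 0.06 in PRH-labelled tumours (n = 4 each, exact permutation p = 0.629). Lymphatic endothelial markers had 0 of 4 past the threshold, too few for a list test. Of 14 fibroblast markers 1 was higher and 2 were lower, led by Pdgfra (-0.73, adjusted p = 0.012, list 0.238). Of 16 macrophage and monocyte markers 3 fell or were lower, among them the chemokine receptor gene Ccr2 (-1.35, adjusted p = 0.00768) and the lysozyme gene Lyz2 (-0.86, adjusted p = 0.0172), and the list's adjusted p was 0.0947. Of 11 NK and cytotoxic markers 2 were lower, led by the activating receptor gene Klrk1 (-1.86, adjusted p = 0.0172, list 0.135). Of 10 dendritic cell markers 2 were higher and 2 lower, with Zbtb46 up by 1.17 (adjusted p = 0.009) but its other probe called in the opposite direction (-0.86, list 0.572).

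The remaining markers were spread in both directions. T cells had 1 of 15 higher (list adjusted p = 0.181) and neutrophils 1 of 15 higher and 1 lower (list 0.618). B and plasma cells had 1 of 11 higher, Sdc1, by 0.99 (adjusted p = 0.0147, lost after median centring, list 0.641). Sdc1 stood at 3.46 in control and 4.45 in PRH-labelled tumours, while the mean of its list was -1.63 and -2.02. Which cells the Sdc1 signal came from was not tested. Pericytes and smooth muscle had 1 of 13 higher and 1 lower (list 0.978), mast cells 0 of 6 (list 0.618), adipocytes 0 of 12 (list 0.618), nerve and Schwann cells 0 of 8 (list 0.284), and normal mammary secretory epithelium 1 of 7 lower (list 0.618). Skeletal muscle had 2 of 15 higher, led by the myosin light chain gene Mylpf (1.31, adjusted p = 0.00686, list 0.618), and erythroid cells 1 of 7, the carbonic anhydrase gene Car1 (1.20, adjusted p = 0.00999, list 0.328). Adjusted over the list alone, the higher and lower counts were 0 and 2 for fibroblasts, 0 and 3 for macrophages, 0 and 1 for NK cells, 2 and 2 for dendritic cells, 1 and 0 each for B cells, skeletal muscle and erythroid cells, and 0 and 0 for the others named in this paragraph.

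The other cell type members given by the rule passed and failed in 4 to 7 of the 8 fits without 1 array, with adjusted p up to 0.118 (Pcolce, without control 5). Lower were the pericyte receptor gene Pdgfrb (-0.66), Gsn of fibroblasts (-0.69), the macrophage receptor gene Mrc1 (-1.16), the neutrophil gene Retnlg (-1.15), the NK receptor gene Klrd1 (-0.83), the dendritic cell genes Clec9a (-1.19) and Flt3 (-1.41, another probe called at 1.31) and the growth factor gene Areg (-1.09). Higher were Tagln of smooth muscle (0.91), Pcolce of fibroblasts (0.48), Csf3r of neutrophils (0.96), Foxp3 of regulatory T cells (0.68), Siglech of dendritic cells (0.66, another probe at -1.19) and Tnni2 of muscle (0.73), none of which passed after median centring. Pcolce, Foxp3 and Siglech passed in the 75th percentile scaling alone, Mrc1 failed in the authors' values, and Retnlg failed there, with normexp and after quantile normalization. With the mouse number as a block, Gsn (adjusted p = 0.0525), Pcolce (0.0544), Klrd1 (0.0594) and Siglech (0.0614) did not pass. With it the T cell gene Cd3e (0.76, adjusted p = 0.0271 against 0.0834), the NK receptor gene Klra8 (-0.86, 0.0342 against 0.0948), the B cell gene Pax5 (0.87, 0.0458 against 0.105) and the muscle gene Pvalb (1.08, 0.0257 against 0.306) passed. So did Lalba (1.10, 0.0186 against 0.114) and Prom1 (0.64, 0.0369 against 0.106) of mammary epithelium and the erythroid gene Slc4a1 (1.42, 0.0097 against 0.156). The block moved the count of higher genes from 1 to 2 each in T cells, B cells and erythroid cells, from 0 to 3 in mammary secretory epithelium and from 0 to 1 in the skin list. It moved it from 2 to 1 in dendritic cells and from 1 to 0 in fibroblasts, where that of lower genes went from 2 to 1. Over all the genes that the rule gives, 108 of 187 passed, of which 58 also passed in every fit without 1 array, 68 in the 4 other scalings, 95 with the block and 44 in all of these.

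Skin and hair follicle genes had the highest median among the lists, with large spread between arrays. In the epithelial adhesion and keratin list 2 of 25 were higher (0 over the list alone, list adjusted p = 0.305), and Krt14, a basal keratin gene, rose by 1.93 (SE 0.452, adjusted p = 0.0192), though without PRH 1 its adjusted p was 0.0516. Krt17 stood at 2.57 (SE 0.897, adjusted p = 0.0721). Krt14 was the 1 of 10 basal mammary markers past the threshold (1 over the list alone, list 0.407). Of 11 skin and hair follicle genes 0 passed (0 over the list alone) with a median difference of 1.97 (list 0.457), and Krtdap, Krt1 and Sbsn, genes of the upper epidermis, stood at 5.61 (SE 2.55, 1 of 4 control arrays above background), 3.08 (SE 1.58, 3 of 4) and 1.98 (SE 0.686, 4 of 4). The mean of the skin list was -0.68, -1.02, -1.80 and -3.48 on PRH arrays 1, 2, 3 and 5 and -4.23, -4.30, -4.92 and -1.07 on control arrays 1, 2, 3 and 5 (exact permutation p = 0.0857). Without control 5 the skin list passed with camera (adjusted p = 0.0472).

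**Figure D4:**
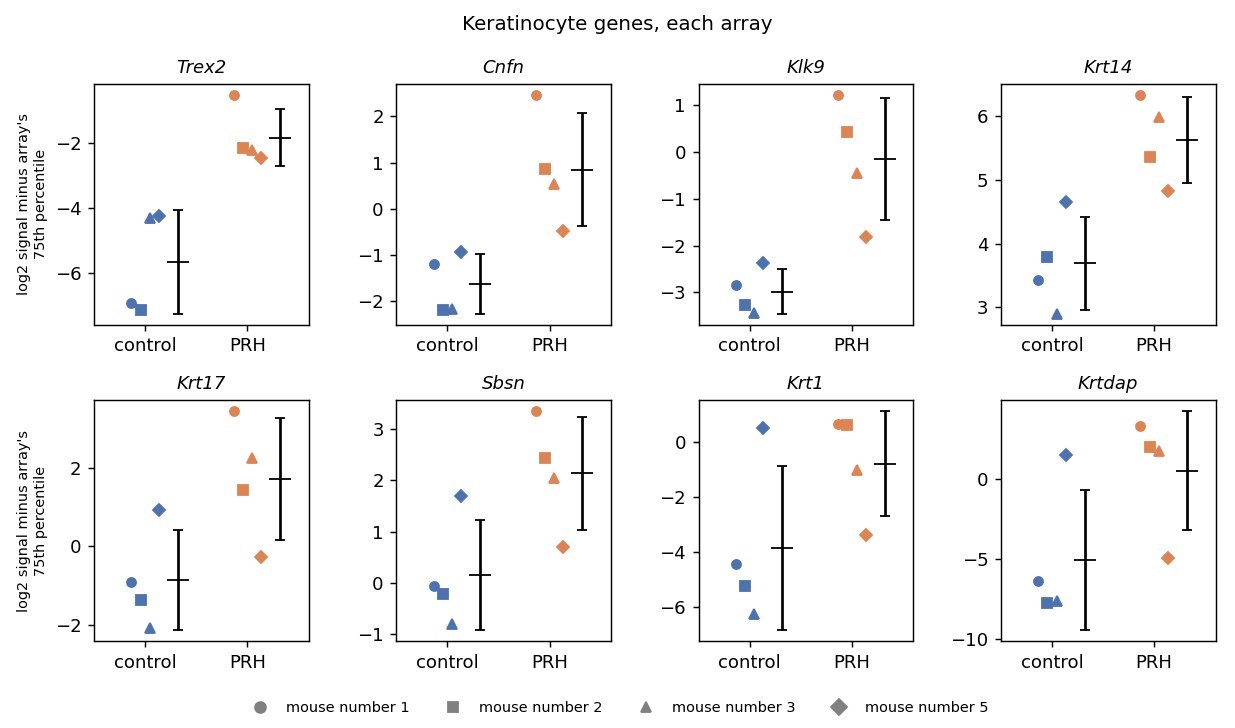
Level of 8 keratinocyte genes on each array (y axis, log2 signal minus the array's 75th percentile; x axis, group), with points for arrays by mouse number and bars for mean ± SD (n = 4). Trex2, Cnfn, Klk9 and Krt14 do not overlap between groups, while control 5 lies among the PRH-labelled arrays for Krt1 and Krtdap.

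The design text of the series takes genes raised in every matched comparison, which was followed with the shared mouse numbers and a limit of 2-fold. At this limit 1855 items were higher in the PRH-labelled tumour in all 4 number-matched comparisons, 403 of them named genes, and 125 were lower, 72 of them named genes. The 23 other ways of pairing the same arrays gave 389 to 1743 higher (median 738), and 167 items were higher in all 16 comparisons. After median centring the count was 224 higher and 577 lower. It was 554 after quantile normalization, 191 with normexp and 241 in the authors' values, and 4684 without mouse number 1. No test was made on these counts.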

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

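The tests on spike-in, control and receptor probes, on Hhex relative to the median of its brightness bin, the exchange of labels and the skin genes were chosen only after the result was seen, and the splits of the arrays and the place of Hhex among genes of its brightness before. In 458 groups of 4 arrays, 26 held an array whose gap to its nearest neighbour, divided by the group's range, was above the 95% critical value of Dixon's test, where chance gives 1 in 20 (22.9). Among list means, control 3 stood above the other controls for collagen and matrix (ratio 0.8697, 3.36 against 3.14 to 3.17), PRH 1 below the others for the p53 response (0.862, 0.906 against 1.04 to 1.07), and control 1 above the others for B and plasma cells (0.9535, 1.36 against -2.74 to -2.55).

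Among single genes, control 1 stood apart for Btla (ratio 0.8636, 0.385 against -1.95 to -1.63), Lmtk2 (0.8896), Lrrd1 (0.9294), Tle4 (0.8474), Ugt2b35 (0.9803), Isg15 (0.8447), Ciita (0.8294) and the B cell gene Cd79b (0.9335, 4.07 against -2.08 to -1.67). Control 2 stood apart for Fzd1 (0.8354), control 3 for Fbn1 (0.9011) and control 5 for Herpud1 (0.8403) and Krtdap (0.8502, 1.49 against -7.74 to -6.36). PRH 1 stood apart for Trex2 (0.8512), Dnajc3 (0.8603), Nop58 (0.845), Pdgfrb (0.8299) and Cd36 (0.9084), PRH 3 for Cabp5 (0.874), Lrrd1 (0.956), Bnip3 (0.8856) and Cr2 (0.833), and PRH 5 for Ciita (0.8294) and Fabp4 (0.9737). Among data not used in the comparisons, the median of 96 synthetic control probes named ERCC was higher on the PRH-labelled arrays by 0.849 (log2 after scaling, -6.93 ± 0.14 in control and -6.08 ± 0.11, n = 4 each, exact permutation p = 0.0286), and by 0.256 without scaling.

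The first pattern is the size of the array-wide difference, with higher scaled readings of dim, unnamed and receptor probes. Chance in how the arrays were split is argued against for the gene count only if they are taken as unpaired. Then only the real split of 35 (1 of 35, the smallest share possible) gave 8934 or more calls, and the highest other gave 509. The rule given above took the mouse numbers as pairs, and with pairs chance cannot be excluded. Among the 8 splits that part all pairs, too few for a share under 0.05, the blocked count was 12232 in the real one (1 of 8) and at most 13 in the others, which mix both labels on each side. Mouse DNA in the PRH RNA stays open: 1459 receptor gene probes, unfiltered, rose by 0.139 more than the 96 control probes, with overlap (exact permutation p = 0.2). With both sets held to those above background on at least 4 arrays, the difference was -0.112 (exact permutation p = 0.743). The 474 receptor genes past that filter rose by 0.862 more than other named genes of their brightness. The 4 PRH-labelled arrays alone can meet the filter. More signal from non-matching RNA stays open too: those control probes rose by 0.849, but all items of the dimmest bin rose by 0.91, and the control probe DCP_1_0 exceeded DCP_1_7, which the files do not describe, by 4.42 on PRH-labelled and 2.73 on control arrays (n = 4 each, exact permutation p = 0.0286). A difference between slide columns in labelling, hybridisation or washing may also be involved, as 5 of 7 spike-in probes differed without overlap relative to their mean. From the dimmest to the brightest, the 7 stood at 0.129, 0.41, 0.104, -0.172, -0.009, -0.424 and -0.037 (PRH-labelled minus control), with overlap for -0.009 and -0.037. Dim items were also higher, at a median of 0.91 in the dimmest bin, against -0.14 in the 8th and 0.07 in the brightest. An effect of PRH itself, on the same split as the slide column, stays open and untested.

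The second pattern is Hhex reading lower where the label puts PRH. Its difference lay at the 4.73 percentile of 1586 named genes of its brightness bin. This lay below their 5th percentile (-1.088 against -1.08), by less than its SE of 0.149. A median shift shared by these genes is argued against as the whole reason: relative to their median Hhex differed by -0.97. It differed by -0.964 to -0.823 after quantile normalization, with normexp and in the authors' values, without overlap (exact permutation p = 0.0286 each). The limma threshold was passed by Hhex itself and was not applied to the difference from the median. Of the 1586 genes 75, Hhex included, had a difference as low or lower, so the median does not set Hhex apart from all of them. An exchange of the group labels could give the same reading (-1.088) and stays open, because no other readout of the delivered gene was used here. A lower native Hhex beside a cDNA the probe does not read is a candidate explanation of the biological kind and was not tested. Nor was it tested whether the delivered gene was still expressed on day 22.

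The third pattern is the keratinocyte genes. Skin carried along with some tumours may account for the upper epidermal genes: within groups, the 11 skin list genes varied together from array to array (median pairwise correlation 0.735), and control 5 (list mean -1.07) read above PRH 3 and PRH 5 (-1.80 and -3.48). Co-variation alone does not point to skin. The correlation that camera estimated was 0.447 for this list, 0.797 for the cell cycle and 0.738 for cholesterol synthesis, and it was lower in some other lists. For Trex2, Lce3c and Cnfn this stays open. With the skin list mean as a term in the fit, 0 of the 3 passed, but 0 items of 34543 passed in that fit (limma, 9592 at an unadjusted p under 0.05), and their median difference went from 3.43 to 2.04, with Trex2 at 3.02 (SE 0.938). Squamous change in the PRH-labelled tumours was not tested, and the co-variation of the skin list genes cannot tell it from carried skin.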

How the results depend on the processing

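Spike-in centring and testing named genes alone were chosen after seeing the data, and the other alternatives before. Unless stated, the cause of a change was not tested. The count of 8934 items became 14698 with array weights, 1 with spike-in centring (limma, 6997 at an unadjusted p under 0.05) and 4255 with named genes alone, where fewer items were tested. It ran from 5733 to 11467 without single arrays, of which 5577 and 8600 were calls shared with the full data in the same direction. The other alternatives stayed within 1.5 times, the mouse number as a block at 12232, of which 8129 were shared. Hhex kept its direction in every alternative run, with -1.158 to -1.003 without single arrays, and lost its call with spike-in centring alone (-1.216, adjusted p = 0.142, range over the alternatives from 0.00151). The 9 list calls became 0 after quantile normalization, with normexp, in the authors' values and with an estimated correlation, 1 with fry, 1 with named genes alone, 2 with probes above background on all 8 arrays, and 3 (without PRH 5) to 13 (without PRH 1) without single arrays, with 5 without control 2. The block moved this count to 10 and changed the 3 list calls given above, and 13 of the 108 genes past the threshold that the rule gives did not pass with it; it changed no call of the other 95.

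The 1855 items in all matched comparisons became 554 after quantile normalization, 191 with normexp, 241 in the authors' values, 224 after median centring, 1100 above background on all arrays, 6032 with a limit of 1.5-fold, 485 with spike-in centring, 403 as named genes alone, and 2160 to 4684 without a mouse number, where fewer comparisons had to pass. Of the 108 genes past the threshold among the 187 given by the rule, 58 also passed in every fit without 1 array, 68 in all 4 other scalings, 95 with the block and 44 in all of these, while all 108 failed with spike-in centring. Of the 79 that did not pass, 9 did with the block. The difference turned sign for some of those 79 and, with the mean of its probes, for Siglech (-0.2652), which alone among them had passed. After quantile normalization it turned for Flt1 (0.05318), Vegfa (0.0711) and Mmrn1 (-0.04364), with normexp for Vegfa (0.1263), Cd74 (-0.1508) and Mmrn1 (-0.3352), and in the authors' values for Vegfa (0.1055), Cd74 (-0.1276) and Mmrn1 (-0.3535). After median centring it turned for Eng (-0.3725), Hspg2 (-0.06908), Cd74 (-0.02087), Hspa8 (-0.0318), Cryab (-0.0217), Tpsb2 (-0.1002), Mcpt4 (-0.2544) and Trp63 (-0.2342). With the mean of a gene's probes it turned for Vegfa (0.1019), Hspa8 (-0.05976), Dnaja1 (0.004506) and Esr1 (0.08462), with array weights for Mmrn1 (-0.378), Mcpt4 (-0.1597), Cidea (-0.03081) and Cd36 (0.04941), and with spike-in centring for Eng (-0.03564). Without single arrays the sign turned within the ranges of Flt1 (-0.137 to 0.03542), Tie1 (-0.3687 to 0.1997), Vegfa (-0.1888 to 0.07039), Eng (-0.08622 to 0.2377), Mmrn1 (-0.4558 to 1.27), Flt4 (-0.4973 to 0.1492), Cpa3 (-0.9504 to 0.01475), Mcpt4 (-0.2215 to 0.6269), Cd36 (-0.674 to 0.04825) and Cfd (-0.2311 to 3.677). The ribosomal protein list, relative to the median of all items, stood at -0.05729 with normexp and -0.05178 in the authors' values, and at 0.1045 after median centring, where camera tested it as lower (adjusted p = 0.995). A block by slide or scan was not run, since there was 1 slide and 1 scan.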

Other observations

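The list calls need the splits of the arrays beside them. With camera, 29 of the 35 splits into 4 and 4 called at least the 9 lists of the real one, and the highest other split, control 1, control 2, PRH 3 and PRH 5 against the rest, called 23 lists. Chance in how the arrays were split can therefore not be excluded for the number of lists. The preset correlation was 0.01, while the estimated one was as high as 0.797 (cell cycle) and gave 0 camera calls. For the gene count the next highest split, mouse numbers 1 and 3 against 2 and 5, called 509.

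The mean of the 7 detected spike-in probes was 12.4 ± 0.40 in control and 12 ± 0.32 on PRH-labelled arrays (unscaled log2, n = 4 each, exact permutation p = 0.2). The median of the 474 receptor genes past the filter, which the 4 PRH-labelled arrays alone can meet, stood at -4.49 ± 0.34 and -3.41 ± 0.16 (log2 after scaling, exact permutation p = 0.0286).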
